A study of Homo sapiens with 38 samples.

How the data were processed

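The series held 38 one-colour Affymetrix arrays of human cells, 18 of the A375 melanoma line and 20 of the clone 16R6-4, in 14 groups of cell line and treatment with 2 or 3 arrays each. Groups, doses and replicate numbers were taken from the labels before the data were examined. The deposited values were linear signal intensities, 1 for each of 54675 probe sets, which the authors made with MAS5, per the submitters' processing notes, which give no version. Per the labels' protocols, cells grew in RPMI1640 medium with 10% serum, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 500 ng of RNA. The values ran from 0.02 to 90603.2, and the mean between the 2nd and 98th percentile was 149.95 to 149.96 on every array, so that the arrays had been scaled to a common trimmed mean. No detection calls were used here. Arrays of a group correlated with r of 0.888 to 0.957 across probe sets (34 pairs), and no arrays were identical.

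Genes were assigned to probe sets with the platform's annotation of 2016, and symbols were checked against RefSeq (GRCh38.p14), where 41043 of 41097 probe sets naming 1 gene were matched and 0 symbols needed an update. Probe sets naming several genes (1801) or none (11777) were left out. Some members of the gene lists, and several RAS and RAF genes of the rule for named genes, were not measured here by a probe set naming 1 gene. Probe sets were kept where at least 2 arrays exceeded the pooled median of 34.88, which left 35888, and the probe set with the highest mean stood for each gene, giving 18063 genes. Values entered the fit as log2 of signal plus 2.8, the 10th percentile of all values.

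A linear model with 14 group means (24 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal (eBayes with trend). The 31 comparisons were the clone against the parental line with DMSO, each of 6 treatments against DMSO in each line, the difference between lines in each of these changes, combinations against single drugs, doses of a drug against each other, and 1 µM GSK436 against 10 nM GSK212. P was adjusted within a comparison by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The 18 gene lists, written before the data were examined, covered ERK output, DNA replication, mitosis, growth-restraining genes, pigmentation, receptor tyrosine kinases, interferon response, antigen presentation, the BCL2 family, cholesterol synthesis, glycolysis, ribosome biogenesis, extracellular matrix, inflammatory cytokines, ATF4 targets with the unfolded protein response, lysosome and autophagy, epithelial markers and leukocyte markers. Of their 333 members 298 were measured. Lists were tested with camera in limma at a preset correlation between genes of 0.01, and again with an estimated correlation, with p adjusted over the lists of a comparison. Where a call was lost with the estimated correlation, that p is given.

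Named genes followed a rule set before the data were examined. It took called genes whose arrays did not overlap between the groups compared (for differences between lines, called genes) and ranked them by fold change. The first 8 in each direction were eligible for the comparison of lines, the higher GSK436 dose and 10 nM GSK212 in each line, the resistant combination at 1 µM and the line difference at 1 µM GSK436, and the first 3 in each direction elsewhere. It added ERK output genes, up to 4 called members of each list, and the genes of the drug targets and of RAS and RAF kinases. Genes on sex chromosomes used to infer sex and genes without a symbol were left out. Of the eligible genes, those printed are a selection made after their values were seen.

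RNA quality was measured by the ratios of 3' to 5' control probe sets for actin and GAPDH. Other settings chosen before the data were examined were quantile normalization, centring each array on its median, no pseudocount or one at the 25th percentile, no filter or one at the 75th percentile (128.16), the mean of all probe sets of a gene, eBayes without trend, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn. Settings added after seeing the data were the log2 actin ratio as a covariate, leaving out arrays with an actin ratio above 20 or a GAPDH ratio above 3, a pseudocount at the median and limma array weights.

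The fit was tested on simulated arrays with 200 of 18063 genes and a gene list changed. For 1 µM GSK436 in parental cells it recovered 44% of genes changed by 1.5 on the log2 scale and 66% of those changed by 2.5, with 6 false calls. For the difference between lines at this dose it recovered 27% and 50%, with 3 false calls, and for resistant cells, where no change was simulated, it made 0 false calls. Data were handled with jsonlite 2.0.0, pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15. Tables were read in R with data.table, version 1.17.8. Plots were drawn with matplotlib 3.10.9.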

Results

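Gene expression was measured on 38 one-colour Affymetrix arrays in A375 human melanoma cells, called parental here, and in 16R6-4, an A375-derived clone selected for resistance to GSK2118436, called resistant here. GSK2118436 (GSK436, dabrafenib) inhibits RAF kinase signalling to MEK and ERK, and GSK1120212 (GSK212, trametinib) inhibits MEK, the kinase that activates ERK. Cells had been exposed for 24 h to DMSO, to 0.1 or 1 µM GSK436, to 10 or 30 nM GSK212, or to 10 nM GSK212 together with 0.1 or 1 µM GSK436. Parental cells gave 3 arrays each for DMSO, 10 nM GSK212 and each combination, and 2 arrays each for 0.1 µM GSK436, 1 µM GSK436 and 30 nM GSK212. Resistant cells gave 2 arrays for DMSO and 3 for each of the other 6 treatments. Every array was scaled to the same trimmed mean signal of 149.95 to 149.96, and the median signal ran from 21.6 to 52.4. The number of arrays limits the precision, and since the labels do not say whether arrays of a group came from separate cultures, each p measures only the spread between these samples. Changes are given as log2 fold changes ± standard error, and a gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. For a gene list the text gives its members called of those measured, the number called when p was adjusted over the list alone, the median log2 fold change and camera's adjusted p over the 18 lists.

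RNA quality differed between the groups. The ratio of the 3' to the 5' actin control probe set, which rises as RNA becomes shorter, ran from 3.72 to 45.0 over the arrays and exceeded 20 on 15 of them. Its mean was 7.76 in parental cells with DMSO (n = 3), 37.3 with 0.1 µM GSK436 (n = 2) and 27.9 with 1 µM GSK436 (n = 2). In resistant cells it was 5.47 with DMSO (n = 2), and with n = 3 each 19.9 and 10.9 with 0.1 and 1 µM GSK436, 22.7 and 20.7 with 10 and 30 nM GSK212, and 8.16 with the combination at 1 µM GSK436. Arrays set apart from their groups in the principal components included replicate 1 of resistant 30 nM GSK212 (ratio 45.0, array weight 0.284) and replicate 3 of resistant 0.1 µM GSK436 (ratio 37.4, weight 0.222). Parental ones included replicate 3 of 10 nM GSK212 (ratio 5.90, weight 0.313), replicate 1 of the combination at 0.1 µM (weight 0.470) and replicate 3 of DMSO (0.446), the reference of the parental changes. The GAPDH ratio exceeded 3 on 4 arrays, both parental arrays with 0.1 µM GSK436 among them. Scaling also set the level of all genes. The median change over all 18063 genes in parental cells lay between 0.17 and 0.39 across the 6 treatments as deposited, and between -0.43 and -0.12 after each array was centred on its median log2 signal. In resistant cells it lay between 0.05 and 0.22 as deposited and between -0.30 and -0.19 after centring.

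**Figure D1:**
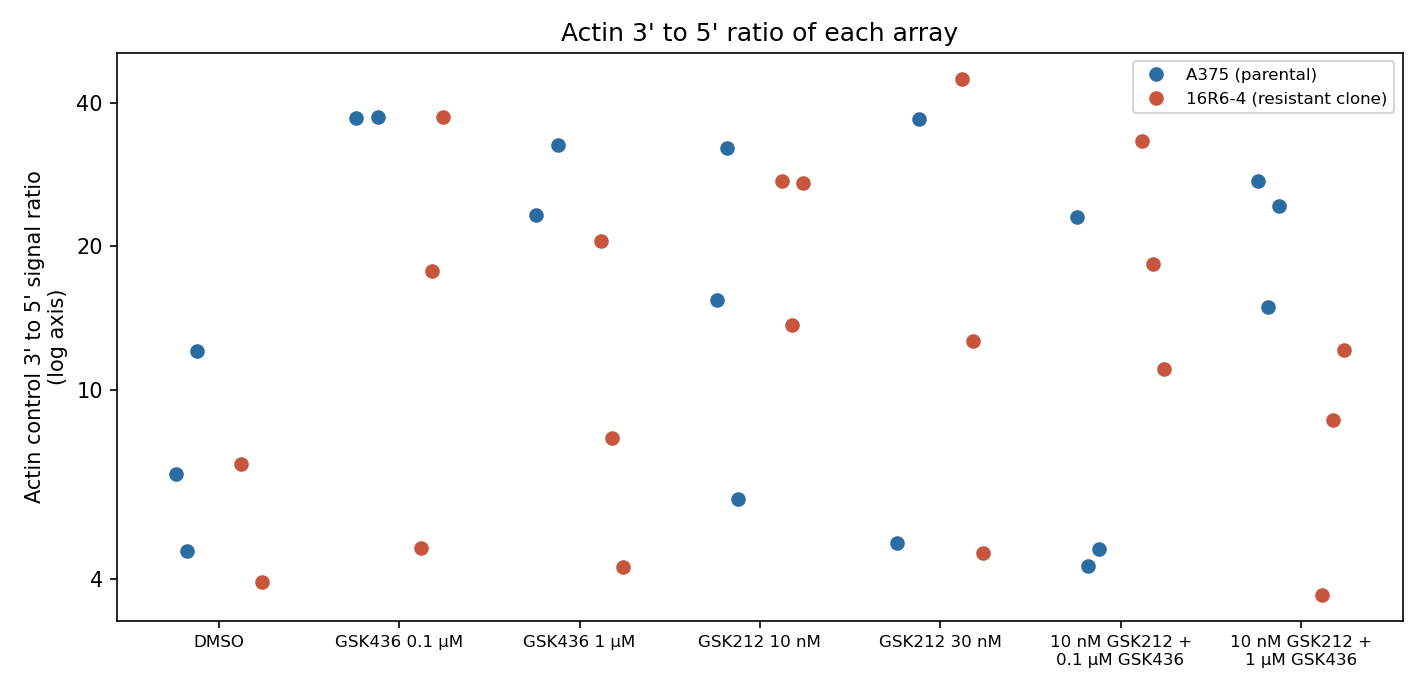
Ratio of the 3' to the 5' actin control probe set on each of the 38 arrays (log axis, no unit) by treatment, with parental and resistant cells in different colours and each point 1 array. Both parental arrays with 0.1 µM GSK436 lie above 37, while the mean of the 3 parental DMSO arrays is 7.76.

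Without drug, the resistant clone differed from parental cells in genes of antigen presentation and the extracellular matrix. SOX10, a transcription factor of the neural crest and melanocyte lineage, was lower (-6.66 ± 0.58, adjusted p = 2.41e-10), as was MIA, a protein secreted by melanoma cells (-6.65 ± 0.52). The MHC class II genes HLA-DRA (-6.41 ± 0.76) and HLA-DRB4 (-5.96 ± 0.53) were lower, as was CD74, the class II invariant chain (-4.44 ± 0.30). KISS1, the kisspeptin precursor known as a metastasis suppressor, was higher by 5.93 ± 0.50, adjusted p = 1.27e-10, and KITLG, the ligand of the receptor KIT, by 4.18 ± 0.37. MITF, the main transcription factor of melanocytes, was also higher (1.73 ± 0.22) although its partner SOX10 was lower.

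In this comparison of 2 resistant with 3 parental DMSO arrays, 657 genes were called, 266 higher and 391 lower. Antigen presentation genes fell as a list (5 of 17 lower, 5 adjusted over the list alone, median -0.59, adjusted p = 1.04e-08), with HLA-DPA1 at -2.42 ± 0.20 and HLA-DMA at -1.70 ± 0.29. Extracellular matrix genes fell as well (3 of 18 higher and 7 lower, 3 and 7 adjusted over the list alone, median -0.94, adjusted p = 0.000112). Tenascin TNC (-2.49 ± 0.29), thrombospondin THBS1 (-2.11 ± 0.24) and collagen COL5A1 (-1.95 ± 0.29) were lower. Periostin POSTN was higher (1.98 ± 0.42). Cholesterol synthesis genes rose (1 of 14 higher, 3 adjusted over the list alone, median 0.26, adjusted p = 0.00525), among them DHCR7, the enzyme of the last step (1.02 ± 0.29). Smaller shifts passed the test for mitosis genes (0 of 21 called, 0 adjusted over the list alone, median -0.19, adjusted p = 0.0499, adjusted p = 0.238 with an estimated correlation), whose median turned positive after centring. They also passed for the BCL2 family (1 of 14 higher, 1 adjusted over the list alone, median 0.24, adjusted p = 0.0499, adjusted p = 0.178 with an estimated correlation) and for ribosome biogenesis (0 of 15 called, 0 adjusted over the list alone, median 0.23, adjusted p = 0.0499, adjusted p = 0.11 with an estimated correlation). Pigmentation genes were not called as a list (1 of 19 higher and 3 lower, 1 and 4 adjusted over the list alone, median -0.45, adjusted p = 0.189). The receptors ERBB3 (-5.02 ± 0.54) and NGFR (-4.10 ± 0.57) were lower within the receptor tyrosine kinase list (2 of 19 lower, 2 adjusted over the list alone, median -0.35, adjusted p = 0.263). ERK output, the list of genes that follow ERK activity, was not called (1 of 21 higher and 1 lower, 2 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.921), and its mean of -0.01 had another sign than the upward direction of the test. Within it the ERK phosphatase gene DUSP5 was higher (2.28 ± 0.28) and the early-response gene IER3 lower (-1.19 ± 0.20). Other genes with large differences were RGS4, a regulator of G protein signalling (4.40 ± 0.65) and CDA, cytidine deaminase (4.24 ± 0.63). Lower ones were collagen COL9A3 (-6.68 ± 0.53) and PMEPA1, a gene induced by TGF-beta (-6.28 ± 0.66). Leukocyte markers, listed as a sign of other cells, gave 1 of 11 lower, 1 adjusted over the list alone, median -0.60, adjusted p = 0.612 here, and 3 of 11 higher, 3 adjusted over the list alone, median 0.73, adjusted p = 0.669 with 1 µM GSK436 in parental cells (CSF1R, GZMB and PTPRC). Called genes were higher in 40.5% as deposited and in 59.1% after centring, and without resistant DMSO replicate 2 the count was 398.

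In parental cells 1 µM GSK436 lowered ERK output and cell cycle genes and raised genes of the ATF4 stress response. DUSP6, the phosphatase that inactivates ERK, fell by 4.83 ± 0.64, adjusted p = 8.27e-07, and the feedback inhibitor SPRY2 (-3.67 ± 0.81), the transcription factor gene ETV5 (-3.45 ± 0.64), MYC (-2.92 ± 0.69) and the cyclin D1 gene CCND1 (-1.88 ± 0.34) fell with it. ASNS, asparagine synthetase, rose by 3.06 ± 0.15, adjusted p = 3.08e-16, with CHAC1, which degrades glutathione (5.06 ± 0.70), and INHBE, an activin subunit (5.52 ± 0.52). MGP, matrix Gla protein, rose by 7.81 ± 0.54, as its mean signal went from 1.57 (n = 3) to 984 (n = 2). A signal this low lies under the pseudocount of 2.8, on which the size of such folds rests.

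For 1 µM GSK436 against DMSO in parental cells (2 against 3 arrays), 3516 genes were called, 2129 higher and 1387 lower. ERK output genes fell (17 of 21 lower, 17 adjusted over the list alone, median -2.44, adjusted p = 5.45e-15), among them the receptor gene EPHA2 (-3.67 ± 0.54), PHLDA1 (-3.06 ± 0.28), DUSP4 (-2.70 ± 0.26) and FOSL1 (-2.55 ± 0.33). Further members that fell were HMGA2 (-2.55 ± 0.23) and SPRED2 (-2.44 ± 0.40). Members not called were FOS (1.12 ± 0.96, adjusted p = 0.396), EPHA4 (0.50 ± 0.83, adjusted p = 0.687), SPRY1 (-0.12 ± 0.58, adjusted p = 0.891) and ETV1 (0.05 ± 0.62, adjusted p = 0.962). With a filter at the 75th percentile another probe set stood for ETV1 and gave -4.15. DNA replication genes fell (11 of 20 lower, 11 adjusted over the list alone, median -1.20, adjusted p = 1.37e-15), with cyclin E2 CCNE2 (-1.97 ± 0.27), the ribonucleotide reductase subunit RRM2 (-1.95 ± 0.17) and PCNA, the polymerase clamp (-1.85 ± 0.23). Mitosis genes fell (13 of 21 lower, 13 adjusted over the list alone, median -1.19, adjusted p = 3.47e-15), with the kinesin KIF11 (-2.32 ± 0.29), the kinase CDK1 (-2.32 ± 0.40) and the spindle checkpoint kinase BUB1 (-1.92 ± 0.26). Ribosome biogenesis genes fell too (5 of 15 lower, 5 adjusted over the list alone, median -0.87, adjusted p = 3.83e-06), with the RNA helicase DDX21 at -2.04 ± 0.24. Inflammatory cytokine genes fell as a list (2 of 16 higher and 6 lower, 2 and 6 adjusted over the list alone, median -0.79, adjusted p = 0.00588), with the chemokines CXCL8 (-4.57 ± 0.89) and CXCL1 (-2.73 ± 0.27) lower and IL6 higher (2.19 ± 0.69). ATF4 target genes rose (10 of 17 higher and 2 lower, 10 and 2 adjusted over the list alone, median 1.07, adjusted p = 7.28e-06), with DDIT3, the factor CHOP (2.58 ± 0.20), and PHGDH of serine synthesis (2.30 ± 0.22). Interferon response genes rose (7 of 19 higher, 8 adjusted over the list alone, median 0.99, adjusted p = 0.0354), with IRF9 (2.43 ± 0.29) and MX1 (2.17 ± 0.39). Further genes with large changes were S100P (6.23 ± 0.71), the stress protein gene NUPR1 (5.74 ± 0.24), the glucose transporter SLC2A12 (5.70 ± 0.49) and keratin KRT13 (5.19 ± 0.80). Lower ones were the transmembrane collagen COL13A1 (-5.87 ± 0.61), the clock factor NPAS2 (-4.96 ± 0.63) and the integrin ITGA2 (-4.23 ± 0.59). Lists without a call included the growth-restraining genes (2 of 12 higher and 1 lower, 2 and 1 adjusted over the list alone, median -0.06, adjusted p = 0.738; mean 0.38), although TXNIP, an inhibitor of thioredoxin, rose (3.65 ± 0.24). Glycolysis was not called either (2 of 18 higher and 3 lower, 2 and 3 adjusted over the list alone, median -0.19, adjusted p = 0.581; mean 0.00, direction of the test down). Of the MEK genes, MAP2K1 fell (-2.23 ± 0.36) and MAP2K2 rose (1.59 ± 0.34), while HRAS (0.35 ± 0.23, adjusted p = 0.263) and ARAF (0.54 ± 0.29, adjusted p = 0.159) were not called. Both arrays had actin ratios above 20, and with that ratio as a covariate 1949 genes were called and 1899 without parental 1 µM GSK436 replicate 3.

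At 0.1 µM GSK436 the parental arrays showed lower ERK output and cell cycle genes without a call for the ATF4 list. DUSP6 fell by 4.91 ± 0.64, adjusted p = 7.98e-07, and ETV5 fell by 4.75 ± 0.64, while MGP (8.00 ± 0.54) and the placental alkaline phosphatase ALPP (5.03 ± 0.34) rose. For this dose 3214 genes were called, 2060 higher and 1154 lower in 2 against 3 arrays. ERK output fell (16 of 21 lower, 16 adjusted over the list alone, median -2.32, adjusted p = 1.81e-15). DNA replication (9 of 20 lower, 9 adjusted over the list alone, median -0.87, adjusted p = 1.84e-12) and mitosis (10 of 21 lower, 10 adjusted over the list alone, median -0.81, adjusted p = 6.43e-10) fell as well. Ribosome biogenesis (median -0.74, adjusted p = 7.99e-07) and inflammatory cytokines (median -0.89, adjusted p = 0.000105) fell and interferon response genes rose (median 1.08, adjusted p = 0.00682). For ATF4 targets the median of -0.07 and the mean of 0.18 differed in sign (3 of 17 higher and 1 lower, 3 and 1 adjusted over the list alone, median -0.07, adjusted p = 0.672). The mean actin ratio of these arrays was 37.3, and the count was 1474 with the ratio as a covariate and 1833 without parental 0.1 µM GSK436 replicate 2.

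The MEK inhibitor gave lower ERK output and replication genes in parental cells together with higher interferon, lysosome and epithelial marker genes. At 10 nM GSK212, DUSP6 fell by 7.12 ± 0.57, adjusted p = 1.61e-11, and ETV5 (-5.68 ± 0.58), EPHA2 (-3.99 ± 0.48) and COL13A1 (-7.07 ± 0.55) fell with it. MGP rose by 9.32 ± 0.48, adjusted p = 3.86e-16, the surface glycoprotein gene CD24 by 5.91 ± 0.17 and the keratin gene KRT14 by 4.18 ± 0.60. FST, the activin-binding follistatin (-4.88 ± 0.24), and NT5E, the ecto-nucleotidase CD73 (-4.59 ± 0.68), fell.

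With 3 arrays on each side, 2116 genes were called, 1387 higher and 729 lower for 10 nM GSK212. ERK output fell (17 of 21 lower, 17 adjusted over the list alone, median -2.66, adjusted p = 1.01e-22), with FOSL1 (-3.65 ± 0.29), DUSP4 (-3.77 ± 0.23), PHLDA1 (-2.93 ± 0.25) and CCND1 (-2.83 ± 0.30) among the called members. DNA replication fell (12 of 20 lower, 12 adjusted over the list alone, median -1.16, adjusted p = 1.31e-19), including the helicase subunit genes MCM2 (-1.62 ± 0.27), MCM3 (-1.50 ± 0.17) and MCM4 (-1.47 ± 0.15). Mitosis (9 of 21 lower, 9 adjusted over the list alone, median -0.95, adjusted p = 7.28e-14) and ribosome biogenesis (6 of 15 lower, 6 adjusted over the list alone, median -0.93, adjusted p = 7.63e-11) fell. Inflammatory cytokines fell (6 of 16 lower, 6 adjusted over the list alone, median -0.83, adjusted p = 0.000303), with IL24 at -3.05 ± 0.34. Interferon response genes rose (11 of 19 higher, 11 adjusted over the list alone, median 1.36, adjusted p = 8.56e-05), with IFITM1 at 2.44 ± 0.40. Epithelial markers rose (4 of 10 higher, 4 adjusted over the list alone, median 1.06, adjusted p = 0.00482), with KRT5 at 4.02 ± 0.81 and SFN, the 14-3-3 sigma gene, at 2.37 ± 0.30. Lysosome and autophagy genes rose (5 of 17 higher, 5 adjusted over the list alone, median 0.59, adjusted p = 0.0107), with the phagophore gene WIPI1 (1.82 ± 0.21) and the lysosomal regulator TFEB (2.32 ± 0.64). Growth-restraining genes rose (3 of 12 higher and 1 lower, 3 and 1 adjusted over the list alone, median 0.77, adjusted p = 0.00405, adjusted p = 0.106 with an estimated correlation), with the cyclin-dependent kinase inhibitor CDKN1C at 3.20 ± 0.68. Antigen presentation genes also passed (3 of 17 higher and 0 lower, 3 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.0242, adjusted p = 0.162 with an estimated correlation). The BCL2 family was not called (2 of 14 higher and 2 lower, 2 and 2 adjusted over the list alone, median 0.15, adjusted p = 0.704, direction of the test down). Its 2 lower members were the death-promoting PMAIP1 (-3.36 ± 0.22) and the survival gene MCL1 (-1.46 ± 0.13). Receptor genes FGFR3 (4.22 ± 0.49) and ERBB3 (2.54 ± 0.48) rose. Other large changes were seen in OLFML2A (5.38 ± 0.46) and EMP1 (-4.24 ± 0.30). The mean actin ratio was 17.8 against 7.76 with DMSO, and limma array weights gave 3960 called genes.

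At 30 nM GSK212 parental cells again had lower ERK output and replication genes, with DUSP6 at -6.18 ± 0.64, adjusted p = 6.74e-09 and MGP at 8.92 ± 0.54. In 2 against 3 arrays 1786 genes were called, 1168 higher and 618 lower. ERK output had a median of -2.58 (adjusted p = 3.76e-24), DNA replication -1.11 (adjusted p = 3.6e-21), mitosis -0.87 (adjusted p = 1.58e-14) and ribosome biogenesis -0.90 (adjusted p = 2.42e-11). Growth-restraining genes rose (7 of 12 higher, 7 adjusted over the list alone, median 1.30, adjusted p = 4.97e-05), with CCNG2 at 2.59 ± 0.40 and TOB1 at 1.55 ± 0.41. Cholesterol synthesis genes rose (3 of 14 higher, 3 adjusted over the list alone, median 0.45, adjusted p = 0.0316), with INSIG1, the sterol-sensing anchor, at 2.21 ± 0.28. Interferon response (median 1.24, adjusted p = 0.000297), lysosome (median 0.47, adjusted p = 0.0174) and epithelial marker genes (median 1.56, adjusted p = 0.00328) also rose. The mean actin ratio was 20.9, and without parental 30 nM GSK212 replicate 3 the count was 1134.

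With either GSK436 dose combined with 10 nM GSK212, ERK output genes were lower than with DMSO in parental cells, and the ATF4 list was called at 1 µM GSK436. DUSP6 fell by 7.56 ± 0.57, adjusted p = 4.81e-12 with the combination at 0.1 µM, and it fell by 5.89 ± 0.57, adjusted p = 1.21e-09 at 1 µM. ASNS rose at 1 µM (2.82 ± 0.14, adjusted p = 5.85e-17), as did MEGF6 (6.07 ± 0.30), while SPRY2 fell at 0.1 µM (-5.73 ± 0.72). With 0.1 µM GSK436, 1913 genes were called, 1258 higher and 655 lower, in 3 against 3 arrays. ERK output (16 of 21 lower, 16 adjusted over the list alone, median -2.63, adjusted p = 4.54e-25), DNA replication (median -1.15, adjusted p = 1.46e-22) and mitosis (median -0.83, adjusted p = 8.42e-15) fell. Growth-restraining genes rose (median 0.95, adjusted p = 0.00032), with the inhibitor CDKN1B at 1.07 ± 0.33. Interferon response (median 1.19, adjusted p = 7.54e-05), lysosome (median 0.49, adjusted p = 0.0426) and epithelial markers (median 1.41, adjusted p = 0.00579) rose as well. With 1 µM GSK436, 3062 genes were called, 2025 higher and 1037 lower, in 3 against 3 arrays. ERK output fell (16 of 21 lower, 16 adjusted over the list alone, median -2.94, adjusted p = 1.49e-20). DNA replication (15 of 20 lower, 15 adjusted over the list alone, median -1.40, adjusted p = 3.62e-22) and mitosis (15 of 21 lower, 15 adjusted over the list alone, median -1.45, adjusted p = 1.49e-20) fell, with KIF11 at -1.87 ± 0.26 and RRM2 at -1.94 ± 0.15. ATF4 targets rose (9 of 17 higher, 9 adjusted over the list alone, median 1.11, adjusted p = 1.39e-08), with CHAC1 at 4.47 ± 0.62 and DDIT3 at 2.07 ± 0.18. Interferon response genes rose (median 1.04, adjusted p = 0.0448). The lysosome list passed with a median of 0.69 (adjusted p = 0.0342), which turned to -0.01 after centring. The mean actin ratio was 10.7 at 0.1 µM and 22.3 at 1 µM, where 2025 genes were called with the ratio as a covariate.

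Scaling moved the share of called genes that were higher in every parental treatment. For 0.1 µM GSK436 that share was 64.1% as deposited, 50.1% after quantile normalization and 10.8% after centring. For 1 µM GSK436 it was 60.5% as deposited, 50.05% after quantile normalization and 13.1% after centring. At 10 nM GSK212 it was 65.5% as deposited and 40.3% after centring, and at 30 nM 65.4% and 27.1%. For the combinations it went from 65.8% to 55.3% with quantile normalization and 24.7% with centring at 0.1 µM, and from 66.1% to 53.3% and 14.6% at 1 µM.

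**Figure D2:**
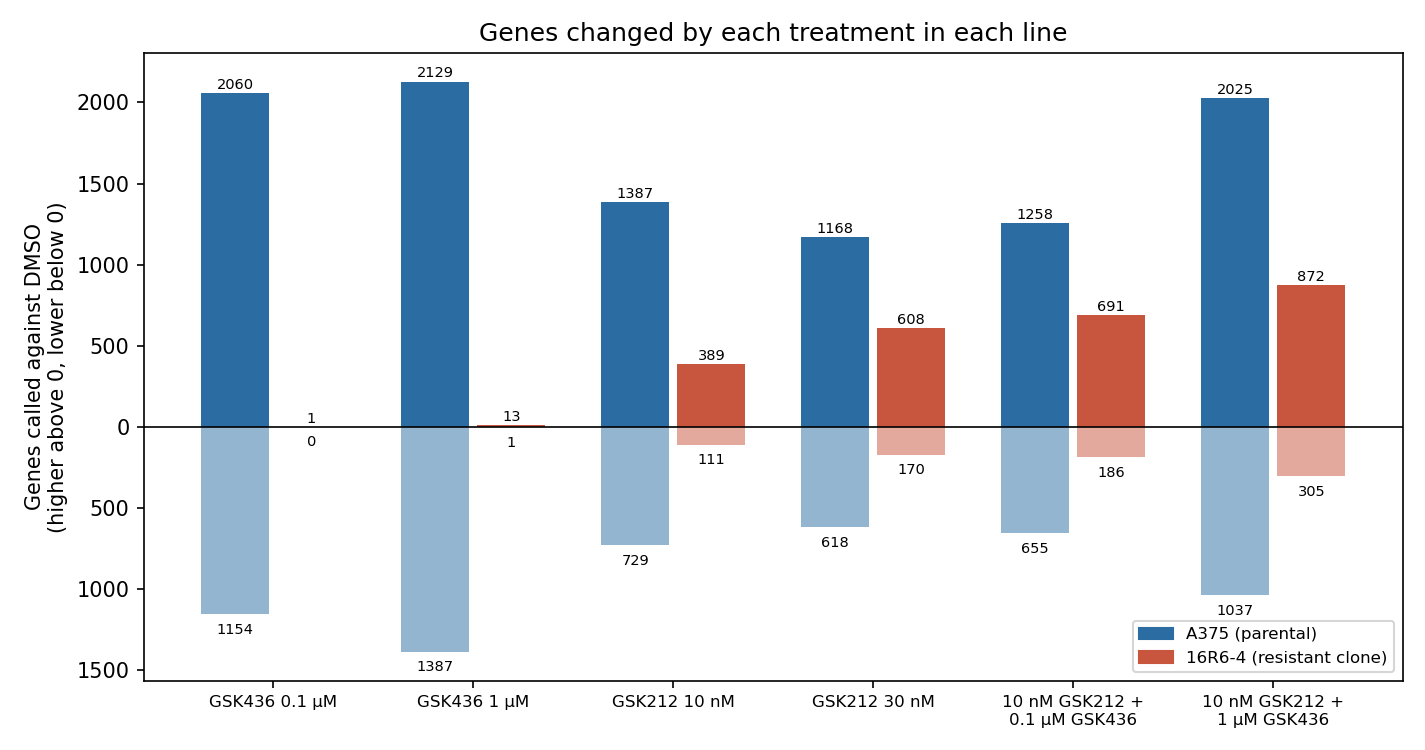
Number of genes called higher (bars above 0) and lower (bars below 0) against DMSO of the same line, by treatment and cell line. Counts with GSK436 alone were 3214 and 3516 in parental cells against 1 and 14 in resistant cells, and the split into higher and lower changes with the scaling of the arrays.

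In resistant cells GSK436 alone left the ERK output genes without a single call, while 1 µM raised genes of the ATF4 response. INHBE rose by 4.34 ± 0.52, adjusted p = 3.99e-06 and ASNS by 1.94 ± 0.15, adjusted p = 6.25e-10. SLC7A11, the cystine transporter (2.22 ± 0.23), DDIT4, an inhibitor of mTOR signalling (1.96 ± 0.23), CTH of cysteine synthesis (2.13 ± 0.34), NUPR1 (2.22 ± 0.24) and PHGDH (1.19 ± 0.22) rose too. DUSP6 had -0.79 ± 0.64, adjusted p = 1, SPRY2 -0.25 ± 0.81, adjusted p = 1 and CCND1 -0.54 ± 0.34, adjusted p = 1.

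At 1 µM GSK436, 14 genes were called, 13 higher and 1 lower, with 590 genes at an unadjusted p under 0.05 in 3 against 2 arrays. The ATF4 list was called (4 of 17 higher, 5 adjusted over the list alone, median 0.82, adjusted p = 1.15e-44). ERK output was shifted down as a list (0 of 21 called, 0 adjusted over the list alone, median -0.39, adjusted p = 0.000211), with DUSP4 at -0.61 ± 0.26, adjusted p = 1 and EGR1 at -1.18 ± 0.67, adjusted p = 1. Glycolysis passed with a small median (0 of 18 called, 0 adjusted over the list alone, median -0.09, adjusted p = 0.0133, adjusted p = 0.109 with an estimated correlation), which was 0.03 without resistant DMSO replicate 1. Other called genes with large changes were LURAP1L (2.62 ± 0.35) and the phosphatase gene PTPRR (-1.49 ± 0.28), the only one lower. Called genes were higher in 92.9% as deposited and in 69.2% after centring. At 0.1 µM GSK436 limma called 1 gene, LURAP1L (2.53 ± 0.35, adjusted p = 0.000401), with 786 genes at an unadjusted p under 0.05, and no list was called. DUSP6 had -0.14 ± 0.64, adjusted p = 0.977 and ETV5 0.02 ± 0.64, adjusted p = 0.999 at this dose, where the mean actin ratio was 19.9 against 5.47. The count at 0.1 µM was 2 without GSK436 replicate 1 or 2, and 20 with array weights, which gave 25 at 1 µM.

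GSK212 at 10 nM lowered ERK output in resistant cells and raised interferon genes. DUSP6 fell by 4.68 ± 0.64, adjusted p = 6.98e-06, and the ERK phosphatase DUSP5 (-3.12 ± 0.28), ETV5 (-3.37 ± 0.64) and CCND1 (-2.39 ± 0.34) fell with it. PTX3, a secreted pentraxin (-3.48 ± 0.22), and ESM1, a secreted proteoglycan (-4.22 ± 0.55), fell as well. MEGF6 rose by 5.61 ± 0.33, adjusted p = 4.36e-14, ALPP by 5.12 ± 0.34, the deiodinase gene DIO2 by 4.58 ± 0.23 and CD24 by 3.77 ± 0.19. The DMSO means of MEGF6, ALPP (2.57, n = 2) and CLIC3 (1.62, n = 2) lay under the pseudocount of 2.8, so the size of their folds rests on it.

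With 3 against 2 arrays, 500 genes were called, 389 higher and 111 lower. ERK output fell (12 of 21 lower, 17 adjusted over the list alone, median -1.91, adjusted p = 3.89e-30), with DUSP4 (-2.46 ± 0.26), EGR1 (-2.65 ± 0.67), EPHA2 (-2.13 ± 0.54), PHLDA1 (-1.80 ± 0.28) and FOSL1 (-1.47 ± 0.33). DNA replication fell (1 of 20 lower, 1 adjusted over the list alone, median -0.25, adjusted p = 0.000126), with CCNE2 at -1.09 ± 0.27, and ribosome biogenesis fell (1 of 15 lower, 2 adjusted over the list alone, median -0.33, adjusted p = 7.24e-05). Inflammatory cytokines passed with a small median (2 of 16 lower, 2 adjusted over the list alone, median -0.05, adjusted p = 0.00709), which was 0.01 without resistant DMSO replicate 2. Interferon response genes rose (4 of 19 higher, 7 adjusted over the list alone, median 1.00, adjusted p = 0.000667), with OAS1 at 1.88 ± 0.44 and IRF9 at 1.69 ± 0.29. Growth-restraining genes rose (2 of 12 higher, 3 adjusted over the list alone, median 0.77, adjusted p = 0.00339, adjusted p = 0.105 with an estimated correlation), with CCNG2 at 2.02 ± 0.40 and CDKN1B at 1.39 ± 0.37. Antigen presentation genes passed (2 of 17 higher, 2 adjusted over the list alone, median 0.38, adjusted p = 0.00339, adjusted p = 0.0789 with an estimated correlation), with the class I regulator NLRC5 at 1.86 ± 0.36 and CD74 at 1.29 ± 0.30, although the list median turned to -0.07 after centring. Cholesterol synthesis genes passed (1 of 14 higher, 1 adjusted over the list alone, median 0.49, adjusted p = 0.0374, adjusted p = 0.0533 with an estimated correlation). Matrix genes were not called as a list (3 of 18 higher and 1 lower, 4 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.062), while collagen COL1A1 (2.46 ± 0.42) rose and CCN2, a matricellular gene, fell (-2.97 ± 0.51). The receptor genes PDGFRB (2.73 ± 0.68), NGFR (2.59 ± 0.57) and ERBB3 (2.30 ± 0.54) rose and EGFR fell (-1.31 ± 0.24). Also changed were CLIC3 (4.37 ± 0.53) and RGS4 (-3.15 ± 0.65). The mean actin ratio was 22.7 against 5.47, and the count was 230 without arrays whose ratio exceeded 20 and 260 without resistant DMSO replicate 2.

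At 30 nM GSK212 the resistant cells also had lower ERK output, with DUSP6 at -5.91 ± 0.64, adjusted p = 4.67e-08 and SPRY2 at -4.21 ± 0.81, while MEGF6 rose by 6.35 ± 0.33. In 3 against 2 arrays 778 genes were called, 608 higher and 170 lower. ERK output fell (15 of 21 lower, 17 adjusted over the list alone, median -2.34, adjusted p = 1.76e-34), with DNA replication (median -0.44, adjusted p = 2.04e-10) and ribosome biogenesis (median -0.44, adjusted p = 2.93e-06). Interferon response (median 0.88, adjusted p = 0.00286), antigen presentation (median 0.56, adjusted p = 0.000392) and growth-restraining genes (median 0.84, adjusted p = 0.00388, adjusted p = 0.111 with an estimated correlation) rose. Cholesterol synthesis passed with 0.43 (adjusted p = 0.0224), but its median was -0.08 after centring. Inflammatory cytokines had -0.04 (adjusted p = 0.0401, adjusted p = 0.08 with an estimated correlation), but 0.07 with array weights and 0.13 without resistant 30 nM GSK212 replicate 3. These arrays had a mean actin ratio of 20.7 against 5.47, and the count was 427 without resistant DMSO replicate 2.

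In resistant cells the combination with 1 µM GSK436 joined low ERK output with a high ATF4 response. DUSP6 fell by 6.15 ± 0.64, adjusted p = 1.19e-08, with CCND1 (-4.23 ± 0.34), ETV4 (-4.69 ± 0.69) and PTX3 (-5.76 ± 0.22). INHBE rose by 6.96 ± 0.52, adjusted p = 5.96e-12, CHAC1 by 4.07 ± 0.70, DDIT4 by 3.30 ± 0.23 and ASNS by 2.72 ± 0.15. MEGF6 rose by 7.07 ± 0.33, and the class I gene HLA-C rose by 1.20 ± 0.14.

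With 3 against 2 arrays, 1177 genes were called, 872 higher and 305 lower. ERK output fell (14 of 21 lower, 16 adjusted over the list alone, median -2.63, adjusted p = 1.57e-30). DNA replication fell (8 of 20 lower, 9 adjusted over the list alone, median -0.80, adjusted p = 1.43e-18), with CDC6 at -1.32 ± 0.19, FEN1 at -1.15 ± 0.17 and cyclin E1 CCNE1 at -1.20 ± 0.23. Mitosis fell as a list (1 of 21 lower, 1 adjusted over the list alone, median -0.39, adjusted p = 9.92e-06), with the kinase gene AURKB at -1.02 ± 0.27. ATF4 targets rose (12 of 17 higher, 12 adjusted over the list alone, median 1.41, adjusted p = 1.65e-22), with SLC7A11 at 2.77 ± 0.23. Antigen presentation rose (6 of 17 higher, 6 adjusted over the list alone, median 0.79, adjusted p = 4.52e-06), with NLRC5 (2.07 ± 0.36) and the immunoproteasome gene PSMB9 (1.06 ± 0.22). Interferon response genes rose (6 of 19 higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.94, adjusted p = 0.00384), with MX1 at 1.88 ± 0.39. Growth-restraining genes rose (6 of 12 higher, 6 adjusted over the list alone, median 0.96, adjusted p = 0.000536, adjusted p = 0.0565 with an estimated correlation). Ribosome biogenesis fell (median -0.53, adjusted p = 1.87e-06). Other large changes were those of ALPP (5.91 ± 0.34), CLIC3 (5.35 ± 0.53), CD24 (5.34 ± 0.19), DIO2 (5.31 ± 0.23) and the chemokine-scavenging receptor ACKR3 (4.98 ± 0.69). Also lower were ESM1 (-5.34 ± 0.55) and RGS4 (-4.45 ± 0.65). The mean actin ratio was 8.16 against 5.47 with DMSO, while ribosomal RNA controls were higher (28S) or lower (18S). With 0.1 µM GSK436 in the combination, 877 genes were called, 691 higher and 186 lower, with DUSP6 at -6.60 ± 0.64, adjusted p = 4.16e-09 and MEGF6 at 6.43 ± 0.33. ERK output fell (15 of 21 lower, 18 adjusted over the list alone, median -2.25, adjusted p = 2.37e-32). DNA replication fell (median -0.50, adjusted p = 1.59e-11) and interferon response genes rose (median 0.80, adjusted p = 0.000438). Antigen presentation rose (median 0.58, adjusted p = 2.81e-05), and mitosis had -0.12 (adjusted p = 0.0442, adjusted p = 0.195 with an estimated correlation), but 0.02 without resistant DMSO replicate 2. ATF4 targets at this dose had 0.31 (adjusted p = 0.0194, adjusted p = 0.0539 with an estimated correlation), and their median was -0.14 after centring. This count was 529 without resistant DMSO replicate 2, and the mean actin ratio was 20.9.

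The share of called genes that were higher in resistant cells also moved with scaling. It was 77.8% as deposited and 26.6% after centring for 10 nM GSK212, and 78.2% and 23.9% for 30 nM. For the combinations it was 78.8% and 30.0% at 0.1 µM and 74.1% and 25.6% at 1 µM.

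**Figure D3:**
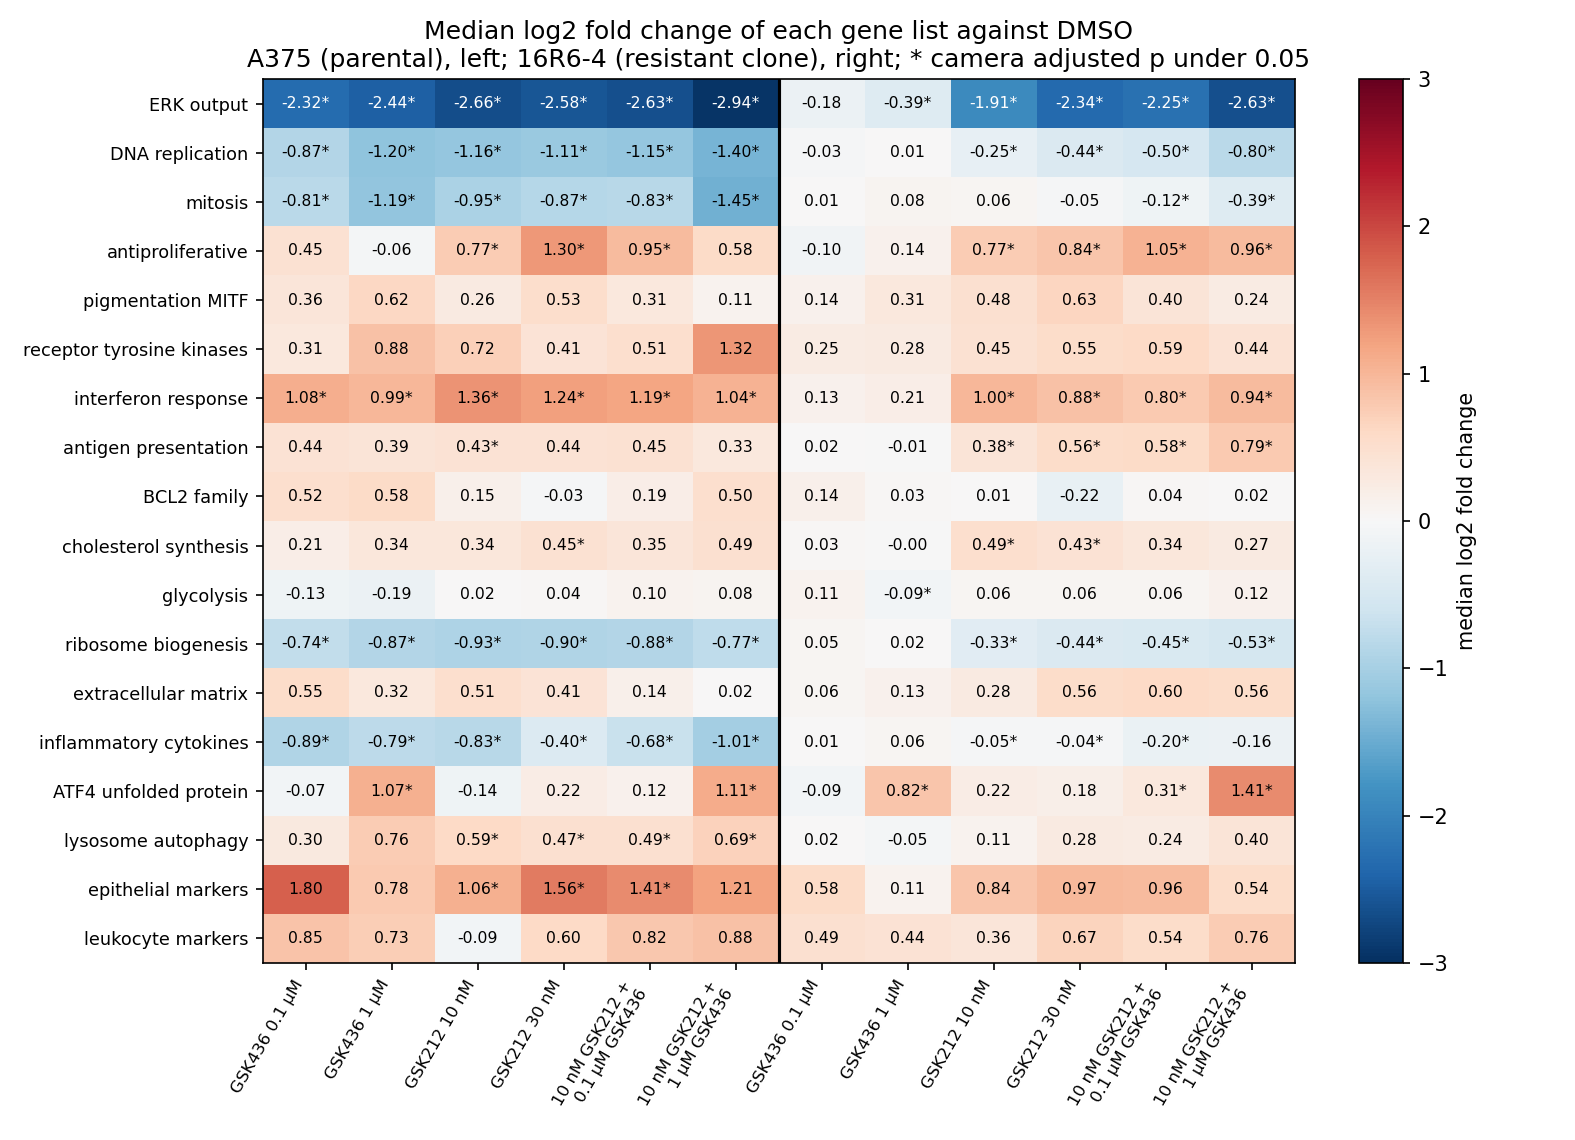
Median log2 fold change against DMSO of each of the 18 gene lists (vertical) for each treatment in parental and resistant cells (horizontal), as a colour scale, with an asterisk at a camera adjusted p under 0.05. ERK output lies between -1.91 and -2.94 wherever GSK212 was present, and after centring the sign turned for the starred lysosome list (parental, combination at 1 µM), antigen presentation (resistant, 10 nM GSK212), cholesterol synthesis (resistant, 30 nM GSK212) and ATF4 targets (resistant, combination at 0.1 µM).

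**Figure D4:**
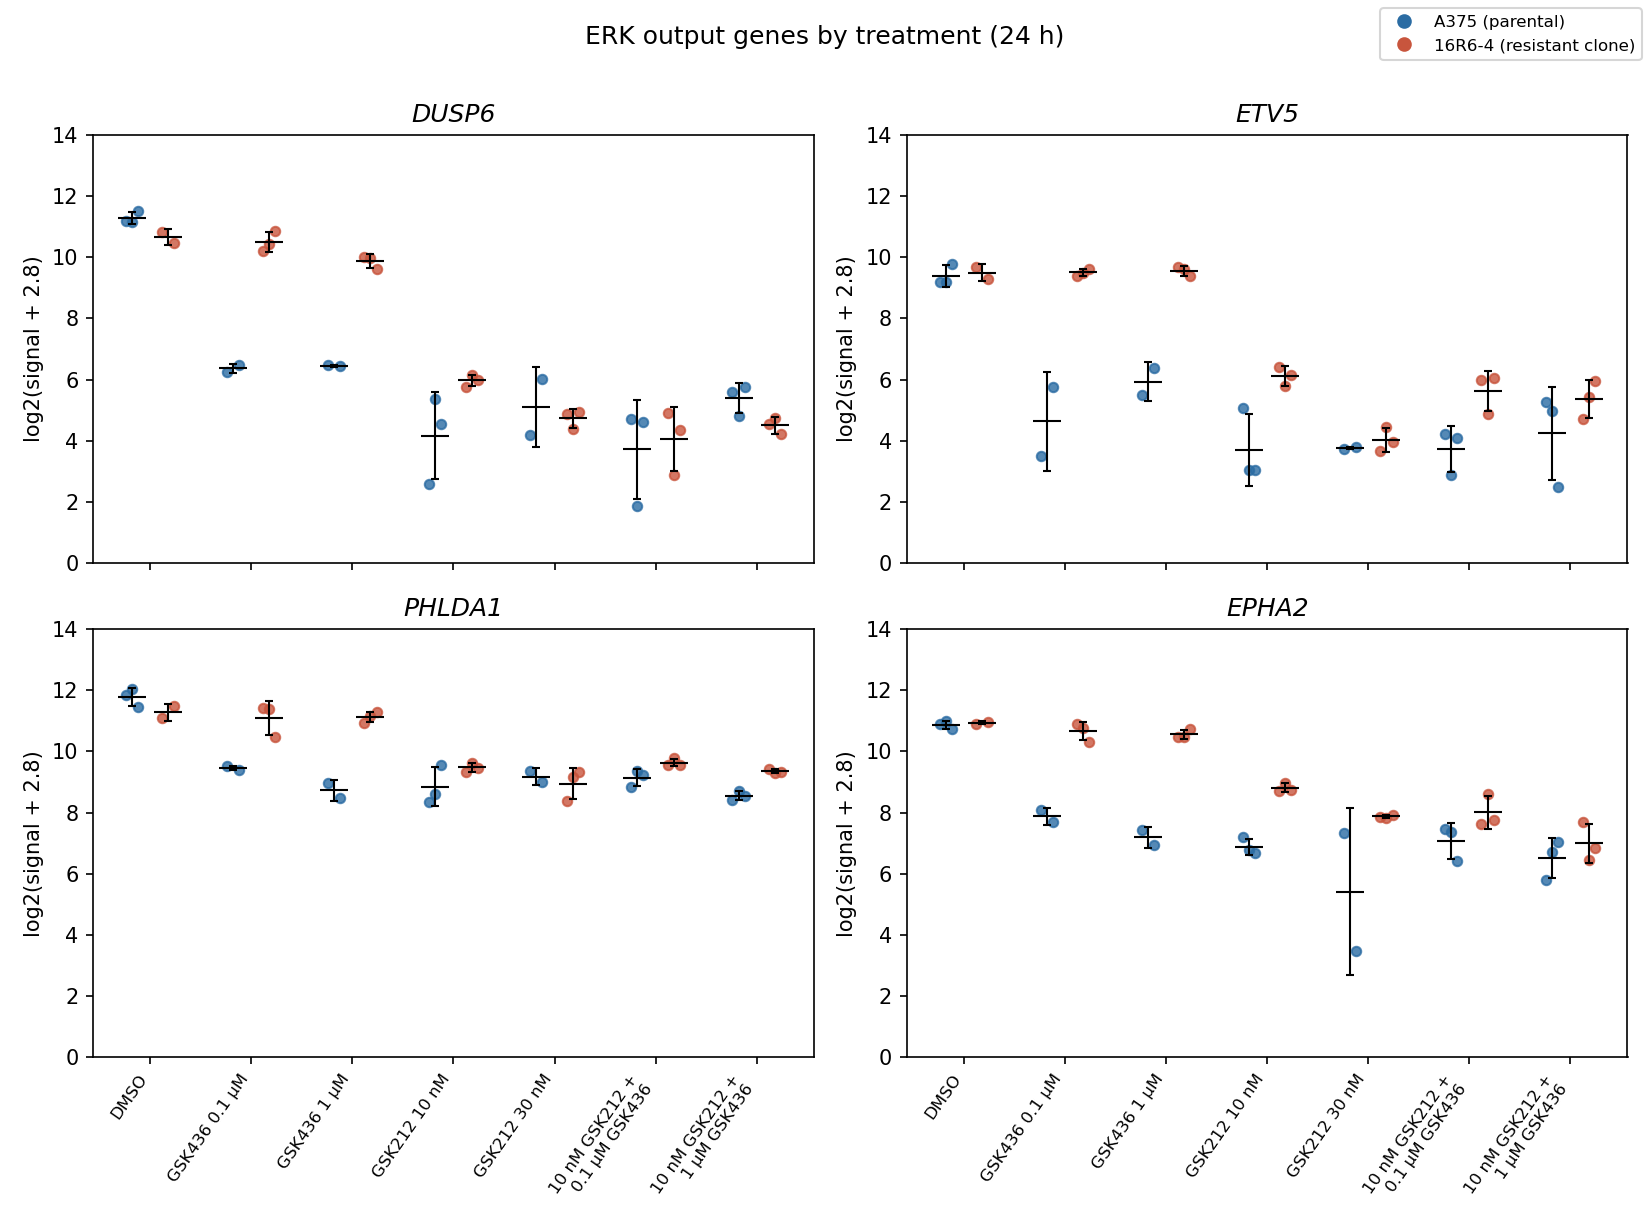
Log2 of signal plus 2.8 on each array for DUSP6, ETV5, PHLDA1 and EPHA2 by treatment, with 1 point per array, colours for the 2 cell lines and bars for mean ± SD. With 1 µM GSK436, DUSP6 changed by -4.83 in parental cells and by -0.79 in resistant cells, where it was not called.

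The responses of the lines were then compared by the difference between resistant and parental changes. ERK output genes responded less to GSK436 in the resistant clone at both doses. At 1 µM the difference was 4.04 ± 0.91, adjusted p = 0.00278 for DUSP6, 2.90 ± 0.40, adjusted p = 7.46e-06 for PHLDA1, 3.28 ± 0.76 for EPHA2, 3.02 ± 0.98 for MYC and 2.64 ± 0.57 for SPRED2. COL13A1 (5.52 ± 0.87), NPAS2 (5.13 ± 0.88) and ITGA2 (4.16 ± 0.84) were called lower in parental cells and not called in resistant cells. MGP (-7.30 ± 0.77), ALPP (-5.28 ± 0.48), S100P (-5.54 ± 1.00) and SLC2A12 (-6.02 ± 0.69) were called higher in parental cells only.

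For 1 µM GSK436, 1981 genes were called, 986 higher and 995 lower, as differences. ERK output differed upward (13 of 21 higher, 14 adjusted over the list alone, median 2.09, adjusted p = 1.64e-11). DNA replication (12 of 20 higher, 12 adjusted over the list alone, median 1.26, adjusted p = 8.09e-15) and mitosis (11 of 21 higher, 11 adjusted over the list alone, median 1.12, adjusted p = 1.69e-14) did too, where RRM2 (2.04 ± 0.24), PCNA (1.99 ± 0.33) and CDK1 (2.65 ± 0.57) stood out. Ribosome biogenesis (5 of 15 higher, 5 adjusted over the list alone, median 0.50, adjusted p = 5.2e-05) and inflammatory cytokines (3 of 16 higher and 1 lower, 5 and 1 adjusted over the list alone, median 0.88, adjusted p = 0.0123) differed upward. Lysosome genes differed downward (7 of 17 lower, 7 adjusted over the list alone, median -0.78, adjusted p = 0.0123). ATF4 targets were not called as a list (1 of 17 higher and 4 lower, 3 and 5 adjusted over the list alone, median -0.18, adjusted p = 0.918). ASNS rose less in resistant cells (-1.12 ± 0.22). DDIT3 (-1.62 ± 0.29) and TXNIP (-3.58 ± 0.35) were called in parental cells only. SLC7A11 (1.74 ± 0.33) was called in resistant cells only (DMSO mean 136, parental 436). At 0.1 µM, 753 genes were called, 343 higher and 410 lower, with ERK output (12 of 21 higher, 14 adjusted over the list alone, median 2.06, adjusted p = 1.52e-15), DNA replication (median 1.04, adjusted p = 7.4e-15), mitosis (median 0.84, adjusted p = 1.16e-10) and interferon response (median -0.60, adjusted p = 0.00638) called. There DUSP6 differed by 4.77 ± 0.91, PHLDA1 by 2.14 ± 0.40 and CXCL1 by 2.86 ± 0.38. Called differences were positive in 49.8% as deposited and 68.2% after centring at 1 µM, and in 45.5% and 69.4% at 0.1 µM. The parental arrays differed from DMSO in actin ratio, as given above, and the 1 µM count was 782, 894 and 1260 without resistant DMSO replicate 1, parental 1 µM GSK436 replicate 3 and parental DMSO replicate 2. The 0.1 µM count was 412, 499 and 1409 without resistant DMSO replicate 1, parental 0.1 µM GSK436 replicate 2 and resistant 0.1 µM GSK436 replicate 3.

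With GSK212 present, mitosis genes differed upward between the lines. AURKA, a mitotic kinase, differed by 1.49 ± 0.20, adjusted p = 1.35e-05 at 10 nM GSK212. DNA replication (6 of 20 higher, 10 adjusted over the list alone, median 1.00, adjusted p = 1.08e-16) and mitosis (6 of 21 higher, 11 adjusted over the list alone, median 1.01, adjusted p = 7.06e-19) differed as lists. MGP (-8.61 ± 0.73), SLC2A12 (-6.35 ± 0.66) and OLFML2A (-6.35 ± 0.70) were called higher in parental cells only, and NTM, a neural adhesion gene, differed by 4.57 ± 0.39. The cytokine gene IL24 (3.10 ± 0.51) and PMAIP1 (2.68 ± 0.32) were called lower in parental cells only. For 10 nM GSK212 343 genes were called, 167 higher and 176 lower, with ERK output differing by a median of 0.75 (adjusted p = 0.000106). At 30 nM 143 genes were called, 72 higher and 71 lower, with mitosis at 0.85 (adjusted p = 6.27e-19), FST at 3.77 ± 0.38 and CD74 at 2.35 ± 0.42. For the combination at 0.1 µM 142 genes were called, 82 higher and 60 lower, with mitosis at 0.72 (adjusted p = 6.77e-15) and EMP1 at 3.38 ± 0.45. For that at 1 µM 190 genes were called, 119 higher and 71 lower, with mitosis at 0.92 (adjusted p = 5.97e-16), antigen presentation at 0.47 (adjusted p = 0.000608), ATF4 targets at 0.36 (adjusted p = 0.0011), SLC7A11 at 2.15 ± 0.31 and HLA-DRA at 4.20 ± 1.01. Differences were positive in 48.7% as deposited and 20.6% after centring at 10 nM GSK212. The 10 nM count was 706 with the actin ratio as a covariate and 119 without arrays whose ratio exceeded 20. Without resistant DMSO replicate 1 the counts were 181 at 10 nM GSK212 and 93 for the combination at 1 µM. Without resistant DMSO replicate 2 they were 221 at 10 nM, 56 at 30 nM and 73 for the combination at 0.1 µM, and the 30 nM count was 83 without parental 30 nM GSK212 replicate 3. Between the lines, 255 genes were called higher in both with 10 nM GSK212 (29.9 if calls were independent) and 83 lower in both (4.48 if independent). For the combination at 1 µM these were 523 (97.8) and 216 (17.5), and for 1 µM GSK436 alone 12 (1.53) and 0.

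In resistant cells the combination at 1 µM, against 1 µM GSK436 alone, had lower DUSP6 (-5.36 ± 0.57, adjusted p = 2.41e-08), DUSP5 (-3.65 ± 0.25), CCND1 (-3.70 ± 0.30) and PTX3 (-5.33 ± 0.20) and higher MEGF6 (7.07 ± 0.30), ALPP (6.18 ± 0.30) and ACKR3 (5.72 ± 0.62). Here 998 genes were called, 735 higher and 263 lower. ERK output fell (15 of 21 lower, 17 adjusted over the list alone, median -2.38, adjusted p = 3.52e-28). DNA replication (7 of 20 lower, 7 adjusted over the list alone, median -0.84, adjusted p = 5.05e-21) and mitosis (median -0.46, adjusted p = 7.55e-07) fell. Antigen presentation (7 of 17 higher, 7 adjusted over the list alone, median 1.02, adjusted p = 2.77e-08), lysosome genes (3 of 17 higher, 3 adjusted over the list alone, median 0.48, adjusted p = 0.00203) and ATF4 targets (median 0.55, adjusted p = 7.55e-07) rose, with GABARAPL1 of autophagy at 1.93 ± 0.25. At 0.1 µM, 834 genes were called, 625 higher and 209 lower, with ERK output (12 of 21 lower, 17 adjusted over the list alone, median -2.07, adjusted p = 4.73e-27) lower, growth-restraining genes higher (median 1.12, adjusted p = 3.58e-06) and DUSP6 at -6.46 ± 0.57. Against 10 nM GSK212 alone the combination at 1 µM had 4.38 ± 0.46, adjusted p = 1.27e-07 for INHBE, 2.70 ± 0.14 for ASNS and -1.84 ± 0.30 for CCND1, and 101 genes were called, 67 higher and 34 lower. There ATF4 targets rose (11 of 17 higher, 11 adjusted over the list alone, median 1.16, adjusted p = 2.27e-45). ERK output (0 of 21 higher and 6 lower, 1 and 9 adjusted over the list alone, median -0.79, adjusted p = 2.48e-10) and DNA replication (median -0.56, adjusted p = 1.01e-19) fell further. Called genes were higher in 73.7% as deposited and 50.8% after centring for the combination against 1 µM GSK436.

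In parental cells, the combination at 1 µM against 1 µM GSK436 had 3 called genes in 3 against 2 arrays: MANEA (3.13 ± 0.50, adjusted p = 0.00386), MMAA (2.52 ± 0.40) and SYBU (2.06 ± 0.40). Limma called 0 after centring, with the mean of probe sets, in the fit of only the groups compared and with a pseudocount at the median (1156, 1410, 1857 and 1835 at an unadjusted p under 0.05), and 24 with the actin ratio as a covariate. ERK output was lower as a list (0 of 21 called, 0 adjusted over the list alone, median -0.59, adjusted p = 0.00257), and 1578 genes had an unadjusted p under 0.05. DNA replication (median -0.23, adjusted p = 0.0327, adjusted p = 0.172 with an estimated correlation) and growth-restraining genes (median 0.32, adjusted p = 0.0327, adjusted p = 0.413 with an estimated correlation) passed too. Against 10 nM GSK212 it raised ASNS (3.30 ± 0.14, adjusted p = 2.67e-18), INHBE (3.93 ± 0.46) and CHAC1 (3.53 ± 0.62) and lowered TGFBI of the matrix (-1.27 ± 0.16), and 62 genes were called, 47 higher and 15 lower. ATF4 targets rose (8 of 17 higher, 8 adjusted over the list alone, median 0.91, adjusted p = 1.57e-27), and mitosis (median -0.44, adjusted p = 8.26e-10) and matrix genes (median -0.28, adjusted p = 0.00043) fell. At 0.1 µM, 228 genes were called, 148 higher and 80 lower against GSK436 alone, with MEGF6 (4.65 ± 0.33, adjusted p = 3.1e-11) and the stress factor ATF3 (2.07 ± 0.24) higher. DUSP6 (-2.64 ± 0.64) and DUSP4 (-1.78 ± 0.26) were lower, and ERK output was lower (4 of 21 lower, 4 adjusted over the list alone, median -0.80, adjusted p = 0.00327). Called genes were higher in 75.8%, 64.9% and 24.1% against GSK212 (as deposited, quantile-normalized and centred; 33 genes without arrays whose actin ratio exceeded 20), and in 64.9% and 77.5% against 0.1 µM GSK436 (as deposited and centred). The mean actin ratios at 0.1 µM were 10.7 and 37.3, and the count of 228 became 24 with the ratio as a covariate, 49 after centring, 38 with the mean of probe sets and 1142 with array weights. It was 63 without parental 0.1 µM GSK436 replicate 2, and 776, 42 and 30 without replicates 1, 2 and 3 of the combination. The count of 3 became 83 and 8 without parental 1 µM GSK436 replicates 2 and 3, and 11 without replicate 1 of the combination.

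Between doses of GSK436, ATF4 targets were higher at 1 than at 0.1 µM in both lines. In parental cells ASNS differed by 3.16 ± 0.17, adjusted p = 5.64e-15, PHGDH by 2.38 ± 0.24, INHBE by 3.41 ± 0.57 and TRIB3, an ATF4-induced pseudokinase, by 1.88 ± 0.21. In resistant cells CHAC1 (3.57 ± 0.62, adjusted p = 0.00294), INHBE (3.06 ± 0.46), DDIT4 (2.45 ± 0.20), SLC7A11 (2.29 ± 0.21) and ASNS (1.96 ± 0.14) were higher and LRRC15 was lower (-3.05 ± 0.51). The ATF4 list was called in parental (5 of 17 higher, 7 adjusted over the list alone, median 0.74, adjusted p = 4.54e-22) and resistant cells (5 of 17 higher, 6 adjusted over the list alone, median 0.79, adjusted p = 6.13e-40). In parental cells 46 genes were called, 35 higher and 11 lower, with mitosis (median -0.34, adjusted p = 4.91e-06) and replication (median -0.22, adjusted p = 0.000857) lower. In resistant cells 20 genes were called, 16 higher and 4 lower, and 8 without arrays whose actin ratio exceeded 20. Called genes were higher in 76.1% as deposited and 97.3% after centring in parental cells, where the count was 108 without parental 1 µM GSK436 replicate 2.

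**Figure D5:**
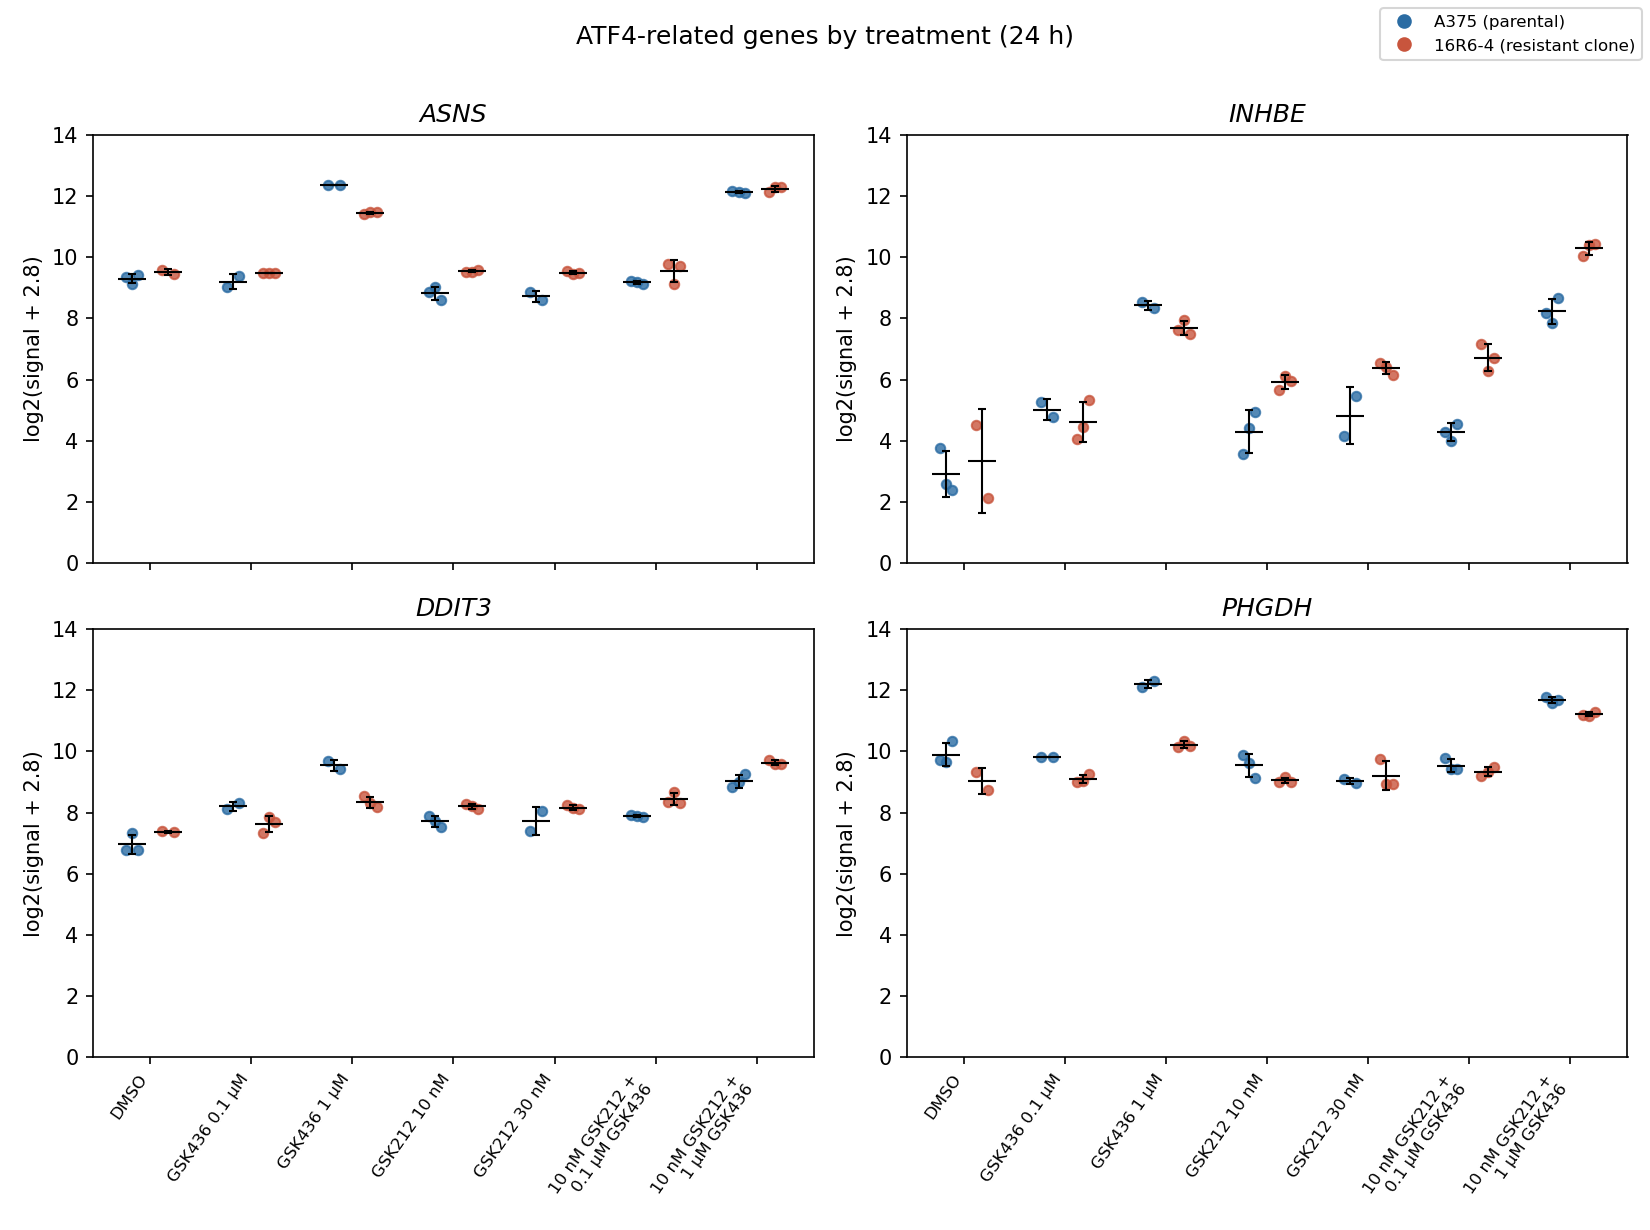
Log2 of signal plus 2.8 on each array for ASNS, INHBE, DDIT3 and PHGDH by treatment, with 1 point per array, colours for the 2 cell lines and bars for mean ± SD. ASNS changed by 3.06 in parental and 1.94 in resistant cells with 1 µM GSK436 against DMSO.

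Between 30 and 10 nM GSK212 limma called 0 genes in each line, with 1196 genes at an unadjusted p under 0.05 in parental and 906 in resistant cells. DUSP6 differed by 0.94 ± 0.64, adjusted p = 0.765 in parental and by -1.23 ± 0.57, adjusted p = 0.971 in resistant cells. In resistant cells ERK output (0 of 21 lower, 1 adjusted over the list alone, median -0.41, adjusted p = 3.84e-08) and replication genes (median -0.23, adjusted p = 1.7e-07) were lower as lists at 30 nM, and no list was called in parental cells. The parental count was 9 without parental 10 nM GSK212 replicate 3 and 23 without parental 30 nM GSK212 replicate 2, and the resistant count was 2 without resistant 10 nM GSK212 replicate 3.

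The inhibitors were also set against each other, 1 µM GSK436 against 10 nM GSK212. In resistant cells ERK output was higher with GSK436, with DUSP6 at 3.89 ± 0.57, adjusted p = 2.27e-05, CCND1 at 1.85 ± 0.30 and ESM1 at 3.46 ± 0.49, while MEGF6 (-5.60 ± 0.30), ALPP (-5.39 ± 0.30) and DIO2 (-3.69 ± 0.21) were lower. There 410 genes were called, 87 higher and 323 lower (180 without arrays whose actin ratio exceeded 20), with ERK output higher (11 of 21 higher, 16 adjusted over the list alone, median 1.65, adjusted p = 1.77e-25). ATF4 targets were higher (5 of 17 higher and 1 lower, 6 and 1 adjusted over the list alone, median 0.62, adjusted p = 4.97e-14), and antigen presentation (median -0.39, adjusted p = 5.34e-05) and interferon response genes (median -0.75, adjusted p = 0.00424) were lower. In parental cells the ATF4 genes ASNS (3.54 ± 0.15, adjusted p = 1.01e-17), PHGDH (2.66 ± 0.22), PSAT1 (2.15 ± 0.21) and CHAC1 (4.12 ± 0.70) were higher with GSK436. There 147 genes were called, 69 higher and 78 lower, with ATF4 targets (7 of 17 higher, 8 adjusted over the list alone, median 0.77, adjusted p = 1.34e-11) higher. ERK output was at 0.50 (adjusted p = 0.0367, adjusted p = 0.0508 with an estimated correlation) and growth-restraining genes at -0.88 (adjusted p = 0.00144, adjusted p = 0.0686 with an estimated correlation). DUSP6 differed by 2.29 ± 0.64, adjusted p = 0.0641. Called genes were higher in 46.9%, 33.7% and 25.2% in parental cells (as deposited, quantile-normalized and centred), and in 21.2% and 38.8% in resistant cells (as deposited and centred). The parental count was 317 and 44 without parental 1 µM GSK436 replicates 2 and 3, and 566 and 57 without parental 10 nM GSK212 replicates 1 and 3.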

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

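Apart from the unfolded protein response in resistant cells, the tests in this part were chosen after the results were seen. Differences between lines in the response to a drug drew attention because the difference itself was tested by limma. There were 753 genes for 0.1 µM GSK436, 1981 for 1 µM GSK436 and 343 for 10 nM GSK212. There were 143 for 30 nM GSK212, and 142 and 190 for the combinations at 0.1 and 1 µM GSK436. A 28S ribosomal RNA control probe set, outside the measured genes, had a mean signal of 30551 ± 4710 (SD, n = 3) with the combination at 1 µM in resistant cells, against 12688 ± 336 (n = 2) with DMSO. Further 28S probe sets had 4026 against 2330 and 41.9 against 6.87, and an 18S one 4974 against 9980. The first had 10660 to 20012 with the other resistant treatments (n = 3 each). No explanation was tested. Groups had 2 or 3 arrays, and no gap test of single arrays was run on groups of that size, while low array weights are given in the report. The excess of genes called higher over lower was also examined and, after its values were seen, was left as values in the report without weighing an explanation.

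ERK output fell with GSK436 in parental cells and less so in resistant cells, by a median difference of 2.09 at 1 µM. Low RNA quality of the parental arrays is argued against as the whole cause, since the difference was 2.097 with the actin ratio as a covariate. That GSK436 did not reach the resistant cultures at 1 µM is argued against by 14 called genes there. At 0.1 µM this stays open, since 1 gene was called, LURAP1L, which was called higher in each of the 6 resistant treatments (2.53 to 4.41) against the same 2 DMSO arrays. That ERK output of the clone no longer responds to 1 µM GSK436 is argued against, since the list was lower there against DMSO (median -0.39) and lower in the combination at 1 µM than with 10 nM GSK212 (-0.785). ERK output of the clone may still depend on MEK, a hypothesis that goes with the median of -1.91 under 10 nM GSK212. Whether the response to 1 µM GSK436 runs through its target, and what in the clone made it smaller, was not tested.

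ATF4 targets rose with 1 µM GSK436 in both lines. RNA quality as the whole cause is argued against by the median of 0.801 in resistant cells with the actin ratio as a covariate, and loss of ERK output by the median of 0.774 for 1 µM GSK436 against 10 nM GSK212 in parental cells. A general unfolded protein response is argued against in parental cells. Its genes HSPA5, HERPUD1, DNAJB9 and XBP1 had a median of -0.929 (-1.01 to -0.11) and the other 13 genes 1.41. In resistant cells it stays open, since these 4 genes had a median of 0.386 between -0.13 and 0.70, against 0.93 for the others. An effect of GSK436 at 1 µM apart from ERK output may account for the rise, in line with the median of 0.794 for 1 against 0.1 µM in resistant cells.

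With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. In 9 of the comparisons with such groups 1 of 10 splits, the real one, gave as many genes. The real count and the highest other were 1913 and 1 (parental combination at 0.1 µM against DMSO) and 3062 and 1 (parental combination at 1 µM against DMSO). They were 62 and 0 (that combination against 10 nM GSK212) and 834 and 1 (resistant combination at 0.1 µM against GSK436). In resistant cells they were also 998 and 1 (resistant combination at 1 µM against GSK436), 101 and 0 (that combination against 10 nM GSK212), and 410 and 1 (resistant 1 µM GSK436 against 10 nM GSK212). For parental 10 nM GSK212 they were 2116 and 1009, where the other split exchanged DMSO replicate 3 and GSK212 replicate 3 and so parted the arrays by actin ratio, a structure of the samples. For resistant 1 against 0.1 µM GSK436 they were 20 and 8, and that split also parted arrays by actin ratio. For resistant 30 against 10 nM GSK212 limma called 0 genes (906 at an unadjusted p under 0.05), the highest other was 1, and 10 of 10 splits gave as many.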

How the results depend on the processing

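Settings based on control probe ratios, a pseudocount at the median and limma array weights were chosen after seeing the data, and the other settings were planned. All 31 counts of called genes stayed within 1.5 times their reported value with the filter at the 75th percentile, without a filter and with a pseudocount at the 25th percentile. Below, "combination 0.1" and "combination 1" are 10 nM GSK212 with 0.1 or 1 µM GSK436, a treatment without a named reference is against DMSO, and "line difference" is resistant minus parental. The cause of a changed count was not tested, except that leaving out arrays leaves fewer samples.

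Quantile normalization gave 2 genes for resistant 0.1 µM GSK436, 313 for resistant 10 nM GSK212. It gave 516 for resistant 30 nM, 535 for resistant combination 0.1, 588 for parental combination 0.1 against GSK436, and 246 for parental 1 µM GSK436 against GSK212. Centring gave line differences of 451 and 1074 genes for 0.1 and 1 µM GSK436. These were 199 and 49 for 10 and 30 nM GSK212, and 58 and 84 for combinations 0.1 and 1. It gave 49 for parental combination 0.1 against GSK436, 62 for resistant combination 1 against GSK212 and 268 for resistant 1 µM GSK436 against GSK212. Centring reversed the median of mitosis at baseline (0.081), lysosome genes in parental combination 1 (-0.012) and resistant 0.1 µM GSK436 (-0.391). It also reversed ribosome biogenesis in resistant 1 µM GSK436 (-0.216), antigen presentation in resistant 10 nM GSK212 (-0.071). Cholesterol synthesis in resistant 30 nM GSK212 (-0.079), ATF4 targets in resistant combination 0.1 (-0.137) and glycolysis in parental 1 µM GSK436 against GSK212 (-0.396) reversed too.

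With the actin ratio as a covariate, 1474, 1949 and 2025 genes were called for parental 0.1 µM GSK436, 1 µM GSK436 and combination 1. Line differences were 706 and 215 for 10 and 30 nM GSK212 and 280 for combination 0.1. Parental combinations 0.1 and 1 gave 24 each against GSK436, resistant combination 1 gave 247 against GSK212, and parental 1 against 0.1 µM GSK436 gave 100. The mitosis median of parental combination 0.1 against GSK436 turned to -0.053. Without arrays with an actin ratio above 20, which removes all parental GSK436 arrays so that their comparisons gave no value, 1917 genes were called for parental combination 1 and 230 for resistant 10 nM GSK212. Line differences were 119 and 70 for 10 and 30 nM GSK212 and 121 for combination 1. This setting gave 33 for parental combination 1 against GSK212, 8 for resistant 1 against 0.1 µM GSK436 and 180 for resistant 1 µM GSK436 against GSK212. Antigen presentation in parental combination 1 against GSK212 turned to 0.058. Without arrays with a GAPDH ratio above 3, which removes both parental 0.1 µM GSK436 arrays, the count was 2199 for parental 1 µM GSK436, 1189 for its line difference. It was 10 for parental combination 1 against GSK436, 62 for parental 1 µM GSK436 against GSK212 and 1 for resistant 30 against 10 nM GSK212.

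Limma array weights moved 19 counts, with 7.61 on resistant 0.1 µM GSK436 replicate 2. They gave 3960 genes for parental 10 nM GSK212, 20 and 25 for resistant 0.1 and 1 µM GSK436. Line differences were 2462, 3421, 1169, 281, 353 and 934 for 0.1 and 1 µM GSK436, 10 and 30 nM GSK212 and combinations 0.1 and 1. Parental combination 0.1 gave 1142 against GSK436 and combination 1 gave 140 against GSK212. Resistant combinations 0.1 and 1 gave 1939 and 1506 against GSK436, and combination 1 gave 224 against GSK212. Between doses the counts were 104 (parental GSK212), 18 (resistant GSK212) and 792 (resistant GSK436), and 1 µM GSK436 against GSK212 gave 244 in parental and 706 in resistant cells. The inflammatory list in resistant 30 nM GSK212 turned to 0.069.

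The mean of all probe sets of a gene gave line differences of 464 and 1229 for 0.1 and 1 µM GSK436 and 81 for combination 0.1, with 38 for parental combination 0.1 against GSK436 and 81 for parental 1 µM GSK436 against GSK212. It reversed ARAF (-1.248) and PPARGC1A (0.197) in parental 0.1 µM GSK436, PAX3 in parental combination 1 (0.521). HEXA (0.202) and ERBB2 (0.463) in the line differences at 0.1 and 1 µM GSK436, SLC2A13 in parental combination 1 against GSK212 (0.5) and the inflammatory list in the line difference of combination 0.1 (-0.098) reversed too. The filter at the 75th percentile, where another probe set stands for the gene, reversed ETV1 in parental 0.1 and 1 µM GSK436 (-3.987 and -4.147) and resistant 10 nM GSK212 (-2.931).

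A fit of only the groups compared gave 288 genes for resistant 30 nM GSK212. Line differences were 180 for 0.1 µM GSK436, 171 and 30 for 10 and 30 nM GSK212 and 295 for combination 1. It gave 472 for parental combination 0.1 against GSK436, 29 for parental combination 1 against GSK212, 425 for resistant combination 0.1 against GSK436. The same fit gave 23 and 5 for 1 against 0.1 µM GSK436 in parental and resistant cells, and 15 for parental 1 µM GSK436 against GSK212. A pseudocount at the median gave 1985 for parental combination 1, 573 for resistant combination 0.1, 521 and 603 for resistant combinations 0.1 and 1 against GSK436, and 244 for resistant 1 µM GSK436 against GSK212. It turned the receptor tyrosine kinase list in the line difference at 10 nM GSK212 to -0.042. No pseudocount gave 5 for resistant 0.1 µM GSK436, and eBayes without trend gave 88 for parental combination 0.1 against GSK436.

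Limma called 0 genes for resistant 0.1 µM GSK436 in the fit of only the groups compared, without arrays with an actin ratio above 20 and with a pseudocount at the median, with 383, 512 and 533 genes at an unadjusted p under 0.05. For parental combination 1 against GSK436 it called 0 after centring, with the mean of probe sets, in the fit of only the groups compared and with a pseudocount at the median, with 1156, 1410, 1857 and 1835.

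The replicate number as a replicate block gave 408 genes for parental combination 0.1 against GSK436 and 231 for parental 1 µM GSK436 against GSK212, and the other 29 counts stayed within 1.5 times. Arrays shared only a number, since 9 of 38 correlated best with their own number.

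Leaving out arrays in turn, where a lone sample was assumed to vary like the other groups, moved 37 counts and left 160 within 1.5 times. Ranges were 398 to 627 at baseline, 1833 to 3788 and 1899 to 4113 for parental 0.1 and 1 µM GSK436, 1134 to 1751 for parental 30 nM GSK212. They were 1 to 5 for resistant 0.1 µM GSK436, 260 to 442 and 427 to 856 for resistant 10 and 30 nM GSK212, and 529 to 771 for resistant combination 0.1. Line differences ranged over 412 to 1409 and 782 to 2707 for 0.1 and 1 µM GSK436, 181 to 476 and 56 to 129 for 10 and 30 nM GSK212, and 73 to 132 and 93 to 276 for combinations 0.1 and 1. Parental combinations 0.1 and 1 against GSK436 ranged over 30 to 776 and 3 to 83, and parental 1 against 0.1 µM GSK436 31 to 108. Ranges of 30 against 10 nM GSK212 were 0 to 23 in parental and 0 to 2 in resistant cells, and parental 1 µM GSK436 against GSK212 gave 44 to 566. The lowest count came without resistant DMSO replicate 2 at baseline (398) and for resistant 10 nM GSK212 (260), 30 nM GSK212 (427) and combination 0.1 (529). The lowest came without parental 0.1 µM GSK436 replicate 2 (1833), 1 µM GSK436 replicate 3 (1899) and 30 nM GSK212 replicate 3 (1134) for those treatments. Medians that reversed ranged from -0.133 (without parental 10 nM GSK212 replicate 3) to 0.131 for glycolysis in parental 1 µM GSK436 against GSK212, and from -0.187 to 0.029 (without resistant DMSO replicate 1) for glycolysis in resistant 1 µM GSK436. Without resistant DMSO replicate 2 the highest were 0.011 for the inflammatory list in resistant 10 nM GSK212 (lowest -0.129) and 0.023 for mitosis in resistant combination 0.1 (lowest -0.176). The inflammatory list in resistant 30 nM GSK212 ranged from -0.07 to 0.129, the latter without its replicate 3.

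With an estimated correlation 37 list calls were lost and 521 list results stayed on their side. Signal over background limits folds from dim genes: MGP had a mean of 1.57 in parental DMSO arrays (n = 3), below the pseudocount of 2.8, so its fold rests on the pseudocount. Other reported genes with a compared group mean below it were ALPP, MEGF6 and KRT13 in parental DMSO arrays and SOX10, HLA-DRB4, COL9A3, NGFR, ALPP, CLIC3, MEGF6, MGP and S100P in resistant DMSO arrays. So were ACKR3, ALPP, LRRC15 and MEGF6 in resistant 1 µM GSK436 arrays.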

Other observations

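The test of gene blocks reported last, and that of RNA quality beside it, were chosen after an earlier result was seen, while the first version of the block test was planned before. Genes that neighbour each other on a chromosome differed together between the untreated lines. Among brighter genes, the 41 genes from VPS16 to RBBP9 had a median difference of -0.66 after centring, and 38 of them had the same sign. The 41 genes from RASA2 to GFM1 had a median of 0.60, with 39 of the same sign, and those from SNAPC5 to SNUPN had -0.57, with 40 of the same sign. Other blocks included those from EFL1 to TM2D3 (-0.56), from DPH6 to ZSCAN29 (-0.55) and from NACA4P to SQLE (0.52).

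A change in copy number of these regions in the clone may account for the blocks, a hypothesis that expression alone cannot settle. The largest absolute median over 41 neighbouring genes was 0.655, against at most 0.421 in 1000 shuffles of gene order. The test was run in 4 versions, and this one was chosen after the first gave 0.769 against a shuffle maximum of 0.965, with 2 of 1000 shuffles as large. The other versions gave 0.752 against at most 0.652 (all genes, centred) and 0.794 against at most 0.617 (brighter genes, centred), over the mean of 7 treatments. That first version used all genes without centring, where the median of all genes was -0.25, and by its own criterion it did not show blocks. Drug effects tested in the same way stayed within their shuffles, at 0.601 against 0.649 in parental and 0.271 against 0.347 in resistant cells. RNA quality is argued against as the whole cause, since the block from VPS16 to RBBP9 had an absolute median of 0.683 with the actin ratio as a covariate.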
